A study of Mus musculus with 8 samples.

How the data were processed

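Pooled neurons of 3 hypothalamic nuclei were profiled on 8 arrays, 2 of Arc, 3 of VMH and 3 of DMH, from 2-month-old female mice. Per the labels, the mice carried an Nkx2-1-CreERT2 driver and a ZsGreen reporter, RNA was isolated with proteinase K and acid phenol, its quality was read on a Bioanalyzer, and the material was labelled chemically with Cy5. Groups and replicate numbers were taken from the labels. The labels give neither the animal behind each sample nor the number of animals.

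The values used are spot intensities of the red channel, background-subtracted and detrended by Agilent Feature Extraction 11.5.1.1, per the file headers, and not normalized between arrays. The flags for spots well above background, saturated spots and outlier spots are also those deposited, per the file headers. All arrays lie on 1 slide and come from 1 scan, so slide and scan cannot act as batches; the row of the slide was tried as a block. The authors' deposited values of the series as a whole hold 55681 entries in 8 columns, but after the first 13 entries each column runs in constant steps (within a tolerance of 1e-04). Their column medians were 10.0725, 795.091, 2696.1, 197.83, -1711.42, 2334.72, -1671.09 and -431.902. Their scale, centring and direction stay unknown, and they were not used.

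Log2 of the processed signal minus the 75th percentile of all non-control spots of the array was taken (59305 spots, 55681 probes). Outlier spots were left out, saturated spots were kept, and spots of a probe were averaged. A probe was kept where it was well above background on every array of at least 1 nucleus, which held for 41500 probes. The brightest probe stood for each gene name, giving 27434 genes, of which 8319 had several probes and 4219 were probes of intergenic transcripts. Among called genes with several probes, a further probe differed in the opposite direction for 2 of 61 in DMH, 3 of 102 in VMH and 0 of 41 in Arc. Names are those of the array design; 15966 of 27434 matched a RefSeq symbol of assembly GRCm38.p6, used for names only. Positions are those of the probes in mm9.

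A linear model with a mean per nucleus was fitted to all 8 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8), leaving 5 residual degrees of freedom. The prior had 2.78 degrees of freedom. Each nucleus was set against the mean of the other nuclei, and each pair was compared, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. The median residual SD was 0.355 on the log2 scale (quartiles 0.237 and 0.539), against a median technical SD of 0.0924 between spots of a probe. Gene lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives.

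The genes named are the 12 largest positive differences of each nucleus past the threshold whose arrays all lie above all other arrays, and the 5 largest in each direction for each pair. To these come up to 4 genes past the threshold from each list, or up to 2 with the smallest p where none passed, and 16 genes fixed in advance. Pdyn in DMH, Tac1 and Hcrtr1 in VMH, and Ghrh and Cartpt in Arc are given as further list members outside this rule. Their differences there were not followed under the alternatives. Names that are only accessions, clones or predicted genes were left out. Some results for genes that the rule names are not reported here. Ppp1r17 was among the fixed genes. The lists, the fixed genes, the tests of genes and lists and their alternatives were set before the data were examined. A correction for the GC content of probes and the tests of Nr5a1, of the glial markers and of the other splits of the samples were added later.

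Alternatives were normexp background correction (offset 50), quantile normalization, a percentile over probes detected on all arrays, other filters on dim probes, a floor, the mean of a gene's probes, trended and robust eBayes, array weights, a block for the replicate number or the slide row, a fold of at least 2, and each array left out in turn. The model was tested on simulated arrays of 27323 genes with 50 genes changed at each of several sizes. Of 50 genes with a log2 change of 1, 12 were recovered in DMH, 12 in VMH and 10 in Arc against the mean of the other nuclei. At a log2 change of 2 these counts were 37, 35 and 36, and at 4 they were 48, 48 and 49. False calls made up 5.23%, 3.36% and 8.28% of calls. The simulated noise was normal, independent between genes and arrays and of the same spread in every nucleus, in 1 draw per comparison. It held no shared animals and no effects of whole arrays, so these shares need not hold for the real calls. At a log2 change of 2 between pairs, 30 of 50 were recovered for DMH against VMH, 21 for DMH against Arc and 28 for VMH against Arc.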

Results

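Gene expression was measured in neurons of the Nkx2-1 lineage from 3 nuclei of the mouse hypothalamus: the arcuate nucleus (Arc), the ventromedial nucleus (VMH) and the dorsomedial nucleus (DMH). Nkx2-1 is a homeobox transcription factor of the developing ventral forebrain. The mice were 2-month-old females in which tamoxifen switched on the green fluorescent protein ZsGreen in cells with an active Nkx2-1 gene, and the green neurons were cut out by laser microdissection and pooled. Arc was represented by 2 samples, VMH by 3 and DMH by 3, each on its own 1-colour array of the same slide. The question of the series was which genes are enriched in the labelled neurons of each nucleus. The labels did not tie samples to animals and did not give the number of animals, so samples may share an animal. The p-values are too small if samples of the same nucleus share an animal. If only samples of different nuclei do, the p-values may instead be too large, as the fit did not pair samples. The p-values measure the spread between these samples, which may be partly technical.

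Between 72.4% and 78.7% of the 55681 probes were well above background on an array, and the number of arrays per nucleus limited the precision. The 75th percentile of the signal was 1818 and 1806 in Arc replicates 1 and 2. It was 2036, 1866 and 1980 in VMH and 3042, 2319 and 2107 in DMH replicates 1, 2 and 3. All DMH arrays were thus brighter than all VMH arrays, and these brighter than both Arc arrays. Arrays of the same nucleus correlated at r = 0.94 to 0.964 over genes and arrays of different nuclei at 0.905 to 0.951. The first principal component held 25.8% of the variance and placed Arc opposite DMH, with VMH between. This is also the order of the nuclei in signal strength, so nucleus and signal strength cannot be told apart on it. The next component held 23.3% and set VMH apart.

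**Figure D1:**
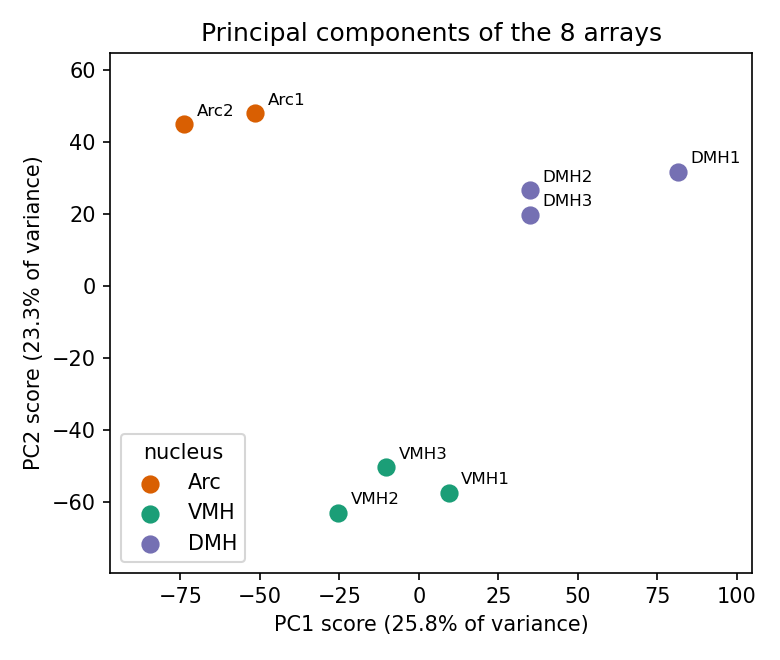
Scores of the 8 arrays on the first principal component (x axis, 25.8% of the variance) and the next (y axis, 23.3%), 1 point per array, coloured by nucleus. The arrays of each nucleus lie together, and DMH replicate 1 lies apart from the other DMH arrays on the x axis.

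Nkx2-1 itself was the basis on which cells were picked and is given only as a check. Its log2 signal, relative to the 75th percentile of each array, was 0.20 ± 0.20 (SD, n = 2) in Arc, 1.12 ± 0.06 (n = 3) in VMH and 1.21 ± 0.08 (n = 3) in DMH. No nucleus passed the test against the mean of the other nuclei (adjusted p = 0.0686 for Arc against the mean of VMH and DMH). All signals below are on this log2 scale. Where a probe was not well above background on any array of a nucleus, its level there is a bound. A difference is given as "at least N-fold" where the probe was not well above background on some or all arrays of the dimmer nuclei. Each such array then entered with the lowest signal among its probes well above background, or with the probe's own signal if higher. This holds for the fold only: the p-values and the choice of the largest differences used signals as measured, dim ones included.

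The first comparison asked which genes the labelled DMH neurons expressed above the mean of Arc and VMH. Among 27418 genes tested, 100 were higher and 130 lower in DMH (limma, Benjamini-Hochberg adjusted p under 0.05), and 4458 had an unadjusted p under 0.05. Grp, the precursor of gastrin-releasing peptide, was at least 51.1-fold higher in DMH (adjusted p = 0.00212; 1.57 ± 0.23 in DMH, n = 3, not well above background on any other array). Its probe lies on chromosome 18 at 66046107 to 66046166 of mouse build mm9. Cck, the precursor of cholecystokinin, was at least 74.4-fold higher (adjusted p = 0.00195), at 3.36 ± 0.10 in DMH and -1.70 ± 0.38 in VMH, and not well above background in Arc. Trh, the precursor of thyrotropin-releasing hormone, was at least 26.8-fold higher (adjusted p = 0.015), as only 1 of the 3 VMH arrays was well above background.

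Prdm13, a PR-domain zinc finger gene, was at least 28.9-fold higher (adjusted p = 0.0172), Skor1, a transcriptional corepressor, at least 33.8-fold (adjusted p = 0.00842) and Ebf3, an early B cell factor gene, at least 8.67-fold (adjusted p = 9.64e-05). Of the forkhead genes, Foxd2 was at least 17.4-fold and Foxp2 at least 16.2-fold higher (adjusted p = 0.0333 and 0.0232). The immediate early gene Egr2 was at least 15.1-fold higher (adjusted p = 0.0211) and the orphan nuclear receptor gene Nr2e1 at least 12.6-fold (adjusted p = 0.0218). Ppp1r17, which encodes a protein phosphatase inhibitor and was followed up in the DMH by the group that made this series, so that its direction is not independent evidence, was 22.6-fold higher (log2 difference 4.5 ± 0.31, SE; adjusted p = 0.00239). Its signal was 1.94 ± 0.67 in DMH, -2.12 ± 0.07 in Arc and -2.99 ± 0.27 in VMH. Fam19a4, a gene for a secreted chemokine-like protein, was at least 18.9-fold higher (adjusted p = 0.014). Of these genes, Prdm13, Foxd2 and Egr2 were well above background on 1 of the 2 Arc arrays, Foxp2 on 1 of the 3 VMH arrays and Fam19a4 on 2 of the 3 VMH arrays.

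Of the 29 fixed gene lists, 8 passed the threshold in DMH (camera with a preset correlation of 0.01), and 2 of these also passed with an estimated correlation. Of 15 measured DMH neuron markers, 7 were higher and none lower (10 and 1 when adjusted over the list alone). The list, which holds Ppp1r17, had a median log2 difference of 1.37 (adjusted p = 1.36e-11, and 0.0202 with an estimated correlation). Besides the genes above, Bsx, a brain homeobox gene, was at least 7.51-fold higher and Pdyn, the precursor of dynorphin, was higher by 1.14. Of 19 Arc markers, 9 were lower and 1 higher (12 and 1 over the list alone; adjusted p = 9.56e-07, and 0.0295 with an estimated correlation), and the gene that was higher was Gal, the precursor of galanin, by 2.11. A gene's differences from the mean of the other nuclei cancel in sum, so a gene high in 1 nucleus alone reads lower in the others. Pomc differed by -2.82 in DMH and -2.80 in VMH, yet by -5.62 and -5.61 against Arc alone. Lower markers of another nucleus thus partly restate their rise in that nucleus, here and in the comparisons of VMH and Arc below. Of 17 VMH markers, 2 were lower, Fezf1 and Sox14 (8 lower and 2 higher over the list alone; adjusted p = 0.000595, and 0.0625 with an estimated correlation). GABAergic neuron genes had a median of 1.12: Dlx1, Gad2 and Dlx2 were 3 of 11 that were higher, by 2.33, 2.00 and 1.70 (6 higher and 2 lower over the list alone; adjusted p = 0.00048, and 0.0625 with an estimated correlation). Neuropeptide receptor genes had a median of -0.60, with 5 of 34 lower, among them Qrfpr, Crhr2 and Mc3r, and 1 higher, Trhr, the receptor gene for thyrotropin-releasing hormone (log2 difference 2.67, adjusted p = 0.0111). Adjusted over the list alone, 16 were lower and 4 higher (list adjusted p = 0.000147, and 0.0709 with an estimated correlation). Neuropeptide genes did not pass as a list in DMH, with 6 of 37 higher and 4 lower and a median of -0.13 (6 and 10 over the list alone; adjusted p = 0.98, and 0.989 with an estimated correlation).

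The circadian clock list had a median of 0.29 in DMH with 1 of 20 genes past the threshold, Rorb, an orphan nuclear receptor gene, at 1.87 (3 over the list alone; list adjusted p = 0.00167, and 0.0927 with an estimated correlation). Voltage-gated potassium channel genes had a median of -0.21, with Kcna1 the 1 of 20 that was lower (4 over the list alone; list adjusted p = 0.0136, and 0.356 with an estimated correlation). That call ended without Arc replicate 1 (adjusted p = 0.115) or DMH replicate 1 (0.109). Astrocyte markers had a median of 0.47, with Gjb6, a connexin gene, the 1 of 13 that was higher, by 1.19 (2 over the list alone; list adjusted p = 0.00167, 0.393 with an estimated correlation, and 0.0772 with fry). The median of the astrocyte markers is to be set beside every gene group that was higher in DMH. The count of 100 genes was 21 without DMH replicate 1, 32 without replicate 2 and 34 without replicate 3 of DMH, and 54, 41 and 57 without VMH replicates 1, 2 and 3. It was also 56 with no filter on dim probes and 36 with the slide row as a block. The count of 130 lower genes was 59, 31 and 42 without VMH replicates 1, 2 and 3, 19, 22 and 39 without DMH replicates 1, 2 and 3, 55 with no filter and 34 with the slide row as a block. Higher genes outnumbered lower ones without VMH replicate 2 or 3 or DMH replicate 1 or 2, with no filter and with the slide row as a block. Of the 12 genes named for DMH only Cck, Ebf3, Grp and Ppp1r17 kept their call under every alternative in which they were tested.

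**Figure D2:**
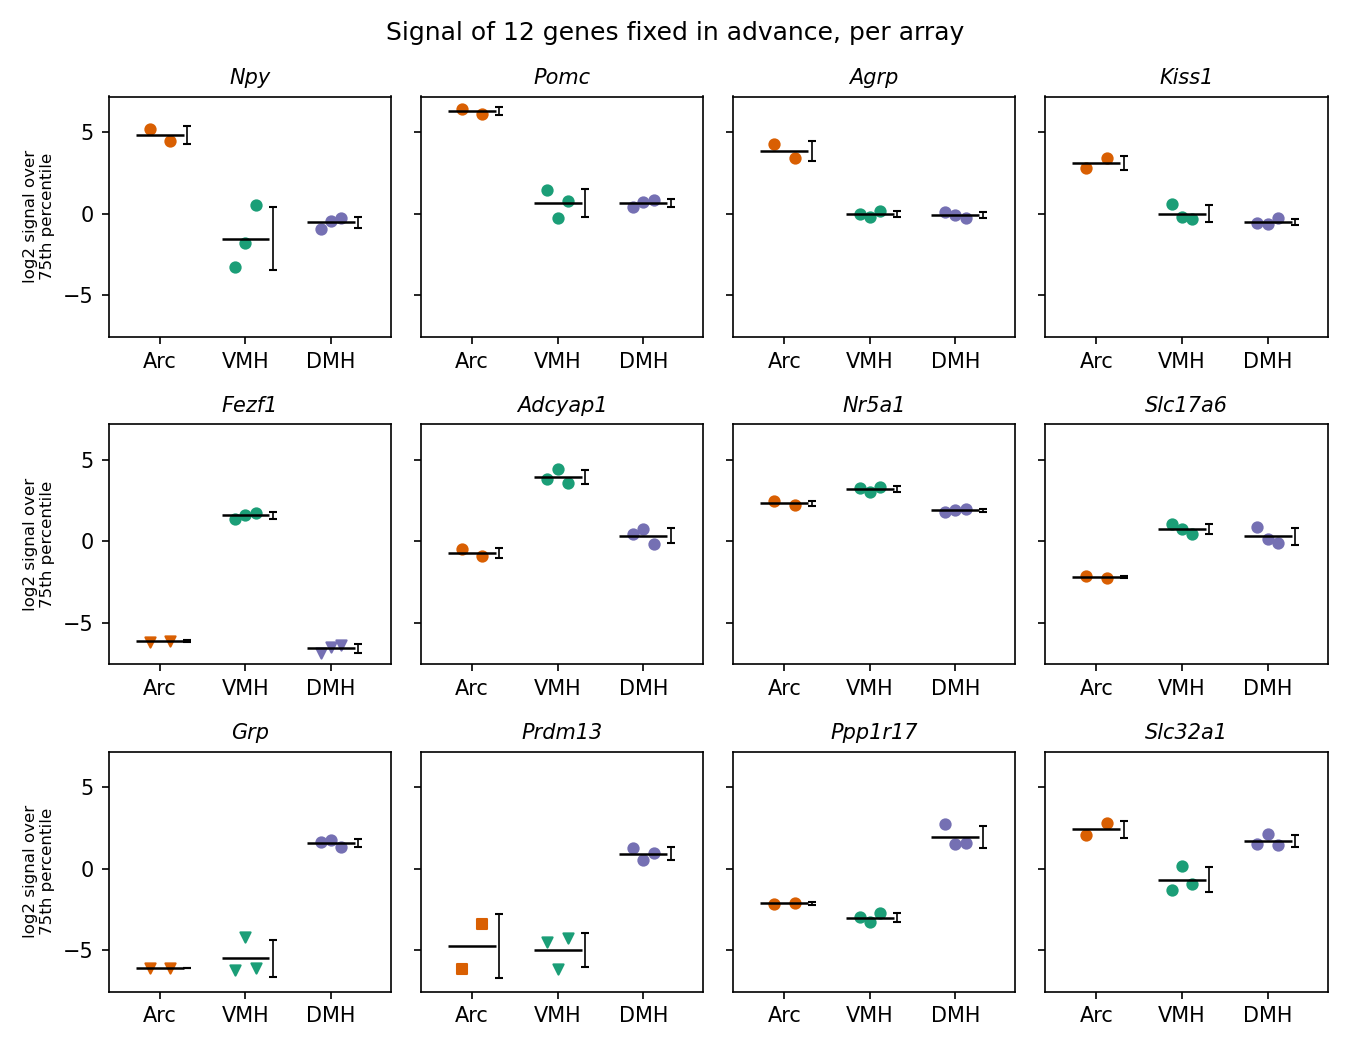
Log2 signal relative to each array's 75th percentile (y axis) of 12 genes fixed in advance, by nucleus (x axis). Each symbol is 1 array (circles, well above background on all arrays of the nucleus; squares, on some; triangles, on none), lines are means and bars ± 1 SD. Fezf1 was at 1.58 in VMH and Grp at 1.57 in DMH, and neither was well above background elsewhere.

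The comparison of VMH with the mean of Arc and DMH called 239 genes higher and 129 lower of 27418. Fezf1, a zinc finger transcription factor gene, was at least 57.5-fold higher in VMH (adjusted p = 6.07e-06; 1.58 ± 0.20, n = 3) and not well above background on any other array. Its probe lies on chromosome 6 at 23195360 to 23195419 (mm9). Kcna1, which encodes the potassium channel Kv1.1, was at least 12.6-fold higher (adjusted p = 0.000331) and likewise below that level on the other arrays. Cbln1, the gene of a secreted synaptic organiser, was at least 39.4-fold higher (adjusted p = 0.00045). Qrfpr, the receptor gene for the peptide QRFP, was at least 28.3-fold higher (adjusted p = 0.00404) and Adcyap1, the precursor of the peptide PACAP, 17.1-fold (4.10 ± 0.29; adjusted p = 0.00162). The other genes named for VMH were Ccnjl (at least 7.89-fold), the vomeronasal receptor gene V1rd19 (at least 5.55-fold), Fam81a (at least 9.9-fold), the neuronal pentraxin gene Nptx1 (at least 10.1-fold), Wdr88 (at least 7.93-fold), Pmfbp1 (at least 4.97-fold) and Iqcj (at least 5.24-fold), with adjusted p between 0.00892 and 0.0487. Cbln1, Qrfpr, Ccnjl and Pmfbp1 were well above background on 1 of the 2 Arc arrays. On the 3 DMH arrays this held for 1 with Qrfpr, V1rd19 and Iqcj and for 2 with Fam81a and Nptx1.

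In VMH 16 of the 29 lists passed, 9 of them also with an estimated correlation. VMH neuron markers had a median log2 difference of 1.53, with 10 of 17 measured genes higher and none lower (12 and 0 over the list alone; adjusted p = 9.94e-16, and 0.00484 with an estimated correlation). Gda, the guanine deaminase gene, was higher by 3.12, Slit3, an axon guidance gene, by 2.79 and Tac1, the precursor of substance P, by 2.74. Nr5a1, the gene of steroidogenic factor 1, was higher by 1.09 ± 0.17 (adjusted p = 0.0269): its single probe read 3.20 ± 0.18 in VMH, 2.33 ± 0.16 in Arc and 1.89 ± 0.08 in DMH. The Nr5a1 call did not hold in 9 of 21 alternatives. Arc markers fell in 9 of 19 genes and rose in 2, Mc3r and Prlr (16 and 2 over the list alone; adjusted p = 2.88e-14, and 0.00484 with an estimated correlation). DMH markers were lower in 6 of 15 (9 over the list alone; adjusted p = 1.08e-12, and 0.00484 with an estimated correlation), among them Bsx, by at least 28.4-fold, which was well above background on 1 of the 3 VMH arrays.

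GABAergic neuron genes were lower in VMH in 6 of 11 measured genes, with a median of -2.46 (7 over the list alone; adjusted p = 6.51e-12, and 0.00484 with an estimated correlation). Of the genes for the enzymes that make GABA, Gad1 was at least 29.2-fold lower and Gad2 differed by -3.76 ± 0.27, the homeobox gene Dlx1 by -3.33 and Slc32a1, the vesicular GABA transporter gene, by -2.73 (adjusted p = 0.0132, 0.00171, 0.00404 and 0.017). Gad1 was well above background on only 1 of the 3 VMH arrays. Among 6 measured glutamatergic genes 1 was higher, Slc17a6, which encodes the vesicular glutamate transporter VGLUT2 (1.68, adjusted p = 0.0299), and 1 lower, Tcf7l2 (-1.57). Slc17a6 read 1.05, 0.72 and 0.43 on the VMH arrays and 0.87, 0.14 and -0.12 on the DMH arrays, which overlap. On the Arc arrays it read -2.155 and -2.232, so its difference came mostly from Arc. Each of these calls was lost in 9 of 21 alternatives. The glutamatergic list did not pass (adjusted p = 0.948). Homeobox transcription factor genes had a median of -0.50, with 7 of 30 lower and none higher (13 and 2 over the list alone; adjusted p = 7.05e-07, and 0.00933 with an estimated correlation). Neuropeptide genes had a median of -0.63, with 7 of 37 lower and 2 higher, Adcyap1 and Tac1 (12 and 2 over the list alone; adjusted p = 2.17e-07, and 0.00791 with an estimated correlation). Steroid and thyroid nuclear receptor genes had a median of 0.45, with Nr2f2, Rxrg and Nr5a1 the 3 of 23 that were higher (7 higher and 1 lower over the list alone; adjusted p = 7.31e-06, and 0.0339 with an estimated correlation). Nr2f2 was also higher in DMH than in the mean of Arc and VMH (3.13, limma adjusted p = 0.00239). Its signal was low in Arc, at least 31.7-fold below VMH and at least 23.8-fold below DMH, so it was not particular to VMH. Ionotropic glutamate and GABA receptor genes had a median of 0.38, although Gabre was lower by a log2 difference of -2.86 and Gabrb1 was the 1 gene of 30 that was higher (0.98; 4 higher and 1 lower over the list alone; list adjusted p = 0.000861, and 0.0354 with an estimated correlation). Markers of paraventricular and suprachiasmatic neurons had a median of -0.65, with Rorb the 1 of 8 that was lower (3 over the list alone; adjusted p = 0.000468, and 0.0376 with an estimated correlation).

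Further lists passed in VMH with the preset correlation alone. Neuropeptide receptor genes had 5 of 34 higher, Qrfpr, Nmbr, Sstr3, Mc3r and Hcrtr1, the last the gene of an orexin receptor (10 higher and 2 lower over the list alone; list adjusted p = 0.0023, and 0.0764 with an estimated correlation). Potassium channel genes had 3 of 20 higher, Kcna1, Kcnq3 and Kcnh3 (5 higher and 1 lower over the list alone; list adjusted p = 0.00149, and adjusted p = 0.122 with an estimated correlation). Of 11 monoamine genes 2 were lower (3 over the list alone), Gch1 by at least 5.33-fold, as it was not well above background in VMH, and Th at a log2 difference of -1.77 (list adjusted p = 0.00352, and adjusted p = 0.0764 with an estimated correlation). Microglia markers had a median of -0.54 and oligodendrocyte markers of 0.45 in VMH, with no single gene past the threshold (2 microglia genes lower over the list alone; adjusted p = 0.000276 and 0.0301, and 0.0764 and 0.307 with an estimated correlation). With fry the oligodendrocyte call ended (adjusted p = 0.141). Both medians are to be set beside the gene groups that differed in VMH. Genes of the mitochondrial respiratory chain had a median of 0.24 and cytosolic ribosomal protein genes of -0.23, again with no single gene past the threshold (adjusted p = 4.18e-06 and 5.68e-07, and 0.0764 and 0.0976 with an estimated correlation). The count of 239 genes was 68, 70 and 58 without VMH replicates 1, 2 and 3, 139 and 135 without DMH replicates 2 and 3, 159 with no filter on dim probes and 140 with the slide row as a block. The count of 129 lower genes was 38, 51 and 54 without VMH replicates 1, 2 and 3, 67 without DMH replicate 3, 78 with no filter and 75 with the slide row as a block. The oligodendrocyte call ended without Arc replicate 2 (adjusted p = 0.0896), VMH replicate 1 (0.0663), VMH replicate 3 (0.173) or DMH replicate 3 (0.0768). Of the 12 genes named for VMH only Adcyap1, Cbln1, Ccnjl, Fezf1, Kcna1 and Qrfpr kept their call under every alternative in which they were tested.

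**Figure D3:**
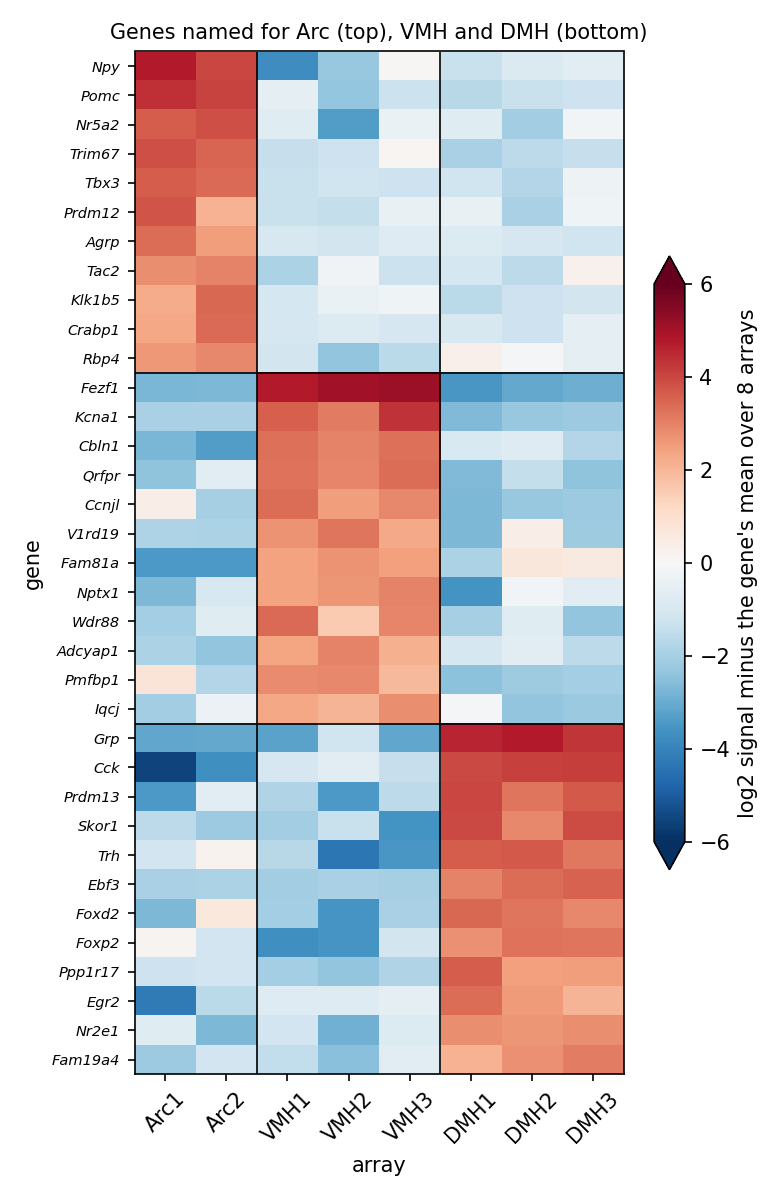
Log2 signal minus each gene's mean over the 8 arrays (colour) for genes named for each nucleus (rows) on the 8 arrays (columns). All arrays of a gene's nucleus lie above all others, which was a condition of choosing it; Npy, at the top, had an SD of 1.92 over the VMH arrays.

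The comparison of Arc with the mean of VMH and DMH called 53 genes higher and 114 lower of 27418. Npy and Agrp, the genes of appetite-stimulating peptides, were 57.7-fold (log2 difference 5.85 ± 0.84; adjusted p = 0.0327) and 14.9-fold (3.90 ± 0.26; adjusted p = 0.00205) higher in Arc. Pomc, the precursor of the melanocortins, was 48.9-fold higher (5.61 ± 0.40; adjusted p = 0.00252). Their signals in Arc were 4.82 ± 0.53, 3.85 ± 0.61 and 6.27 ± 0.23 (n = 2). The Pomc probe lies on chromosome 12 at 3960413 to 3960472 (mm9). The Npy call did not hold in 10 of 21 alternatives, with an adjusted p between 0.00467 and 0.118 over all 21, and its signal in VMH was -1.53 ± 1.92 (n = 3). Tac2, the precursor of neurokinin B, was 14.2-fold higher (adjusted p = 0.0327) and Kiss1, the precursor of kisspeptin, was higher by 3.35 (adjusted p = 0.00634).

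Transcription factor genes named for Arc included Nr5a2 (at least 26.7-fold, adjusted p = 0.0482), Tbx3 (25.6-fold, 0.00257) and Prdm12 (at least 15.0-fold, 0.0392). Crabp1, the gene of a retinoic acid binding protein, was 13.8-fold higher (adjusted p = 0.00331) and Rbp4, the gene of a retinol binding protein, at least 7.7-fold (0.00817). The ubiquitin ligase gene Trim67 was at least 9.44-fold higher (0.0035) and the kallikrein gene Klk1b5 at least 3.63-fold (0.00809). Nr5a2 and Prdm12 were well above background on 2 of the 3 arrays of VMH and of DMH, and Rbp4 on 2 of the 3 DMH arrays. The limit for Prdm12 was 8.25-fold without Arc replicate 1 and 27.1-fold without Arc replicate 2, and its call did not hold in 10 of 20 alternatives. The limit for Klk1b5 was 5.52-fold and 2.38-fold without these arrays. Nr2f2, an orphan nuclear receptor gene, went the other way: it was at least 27.4-fold lower in Arc (adjusted p = 8.97e-05), and Nr2f1, its close relative, had a log2 difference of -2.94 (adjusted p = 0.00205).

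In Arc 12 of the 29 lists passed, 2 of them also with an estimated correlation. Arc neuron markers had a median of 2.05, with 11 of 19 genes higher and none lower (18 and 0 over the list alone; adjusted p = 1.34e-23, and 0.00282 with an estimated correlation). Besides the peptides above, Ghrh, the precursor of growth hormone-releasing hormone, was higher by 2.95 and Cartpt, the precursor of the CART peptide, by 2.82. VMH markers were lower in 6 of 17 (10 lower and 1 higher over the list alone; adjusted p = 6.17e-08, and 0.0211 with an estimated correlation), among them Slc17a6, at a log2 difference of -2.71. GABAergic genes had a median of 1.01, with 1 of 11 higher and none lower (7 higher and 1 lower over the list alone; adjusted p = 8.8e-05, and 0.0597 with an estimated correlation). Homeobox genes had a median of 0.61, with 3 of 30 higher, among them Otp and Six6, and 1 lower, Tshz2 (15 higher and 5 lower over the list alone; adjusted p = 0.00141, and 0.0669 with an estimated correlation). Neuropeptide genes were higher in 8 of 37 and lower in 3, Cck, Grp and Adcyap1 (12 and 7 over the list alone; adjusted p = 0.0201, and 0.112 with an estimated correlation). This list call ended without Arc replicate 1 (adjusted p = 0.169), Arc replicate 2 (0.159) or VMH replicate 3 (0.0659).

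Other lists passed in Arc with the preset correlation alone. The circadian clock list had a median of -0.31 with no gene past the threshold (adjusted p = 0.00975, and 0.121 with an estimated correlation). Ionotropic receptor genes had a median of -0.28, with Gria3 and Grin3a the 2 of 30 that were lower (7 lower and 2 higher over the list alone; list adjusted p = 0.0268, and adjusted p = 0.121 with an estimated correlation). Markers of paraventricular and suprachiasmatic neurons had a median of 0.70, with Six6 the 1 of 8 that was higher (4 over the list alone; list adjusted p = 0.0235, and adjusted p = 0.126 with an estimated correlation). Respiratory chain genes had a median of -0.24 and ribosomal protein genes of 0.25, with no gene past the threshold (adjusted p = 1.18e-06 and 2.48e-05, and 0.112 and 0.203 with an estimated correlation). Astrocyte and oligodendrocyte markers had medians of -0.30 and -0.29 in Arc (adjusted p = 0.0285 for each, 0.44 and 0.337 with an estimated correlation, and 0.155 for each with fry), to be set beside the groups that differed in Arc. Without Arc replicate 2 their adjusted p was 0.371 and 0.313, without VMH replicate 3 it was 0.0734 for each, and without DMH replicate 2 it was 0.062 and 0.0635. The astrocyte call also ended without DMH replicate 3 (0.0503). The clock call also ended without Arc replicate 2 (0.159) and the ionotropic call without Arc replicate 1 (0.169). The paraventricular call ended without Arc replicate 1 (0.125), Arc replicate 2 (0.106), VMH replicate 3 (0.117) or DMH replicate 3 (0.146). The count of 53 genes was 94 and 152 without Arc replicates 1 and 2, 25, 33 and 23 without VMH replicates 1, 2 and 3, and 25, 20 and 30 without DMH replicates 1, 2 and 3. It was 132 with normexp background correction, 100 with a floor on dim values, 92 with trended and robust eBayes, 32 with no filter on dim probes, 29 with array weights and 23 with the slide row as a block. Without Arc replicate 2 the balance turned to 152 higher and 136 lower. The count of 114 lower genes was 47, 51 and 47 without VMH replicates 1, 2 and 3 and 65, 38 and 56 without DMH replicates 1, 2 and 3. It was 185 with trended and robust eBayes, 68 with array weights, 57 with no filter and 56 with the slide row as a block. Of the 12 genes named for Arc only Agrp, Crabp1, Klk1b5, Pomc, Tbx3 and Trim67 kept their call under every alternative in which they were tested.

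**Figure D4:**
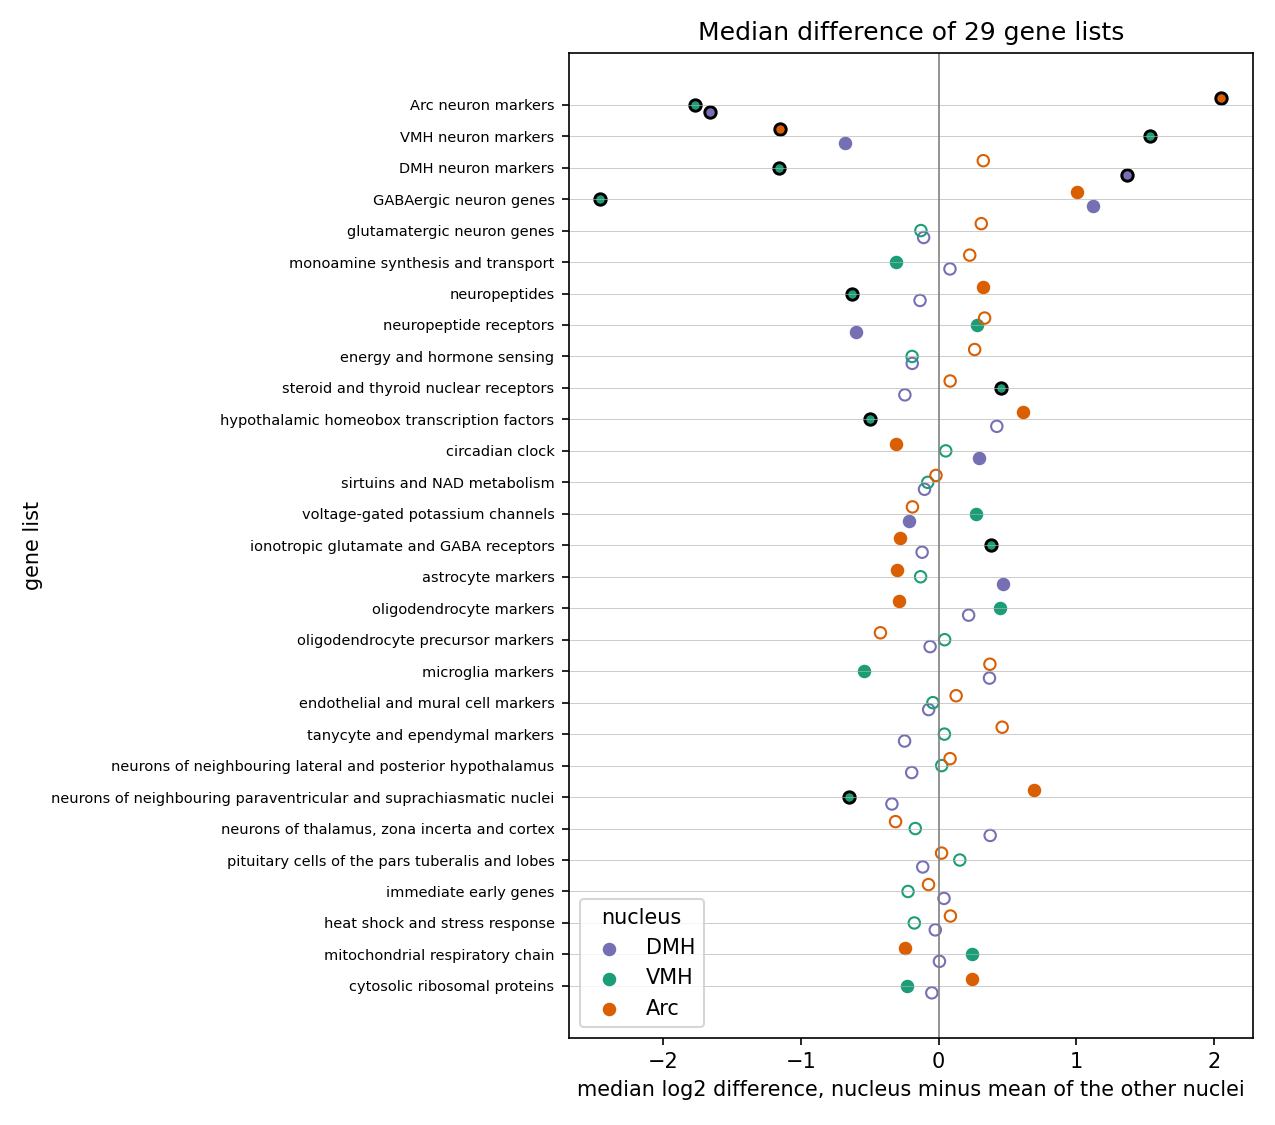
Median log2 difference (x axis) of the measured genes of each of the 29 lists (y axis), for each nucleus against the mean of the other nuclei (colour). Filled points passed camera with the preset correlation and black rims mark those that also passed with an estimated correlation: 2 in DMH, 9 in VMH and 2 in Arc.

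Of the 29 lists, 11 passed in no nucleus: glutamatergic genes, energy and hormone sensing genes, and sirtuins and NAD metabolism. The same held for markers of oligodendrocyte precursors, endothelial and mural cells, tanycytes and ependyma, neurons of the lateral and posterior hypothalamus, neurons of thalamus, zona incerta and cortex, and pituitary cells. Immediate early and heat shock genes were also among these 11. Single genes of these lists did pass: Prlr, the prolactin receptor gene, differed by -1.47 in DMH and by 1.2 in VMH, and Nptx2, a neuronal pentraxin gene, by -2.76 in Arc. Crym was higher in VMH by 1.84, and the tanycyte marker Col23a1 differed by -1.83 in DMH. Gpr50, of the same tanycyte list, went the other way, by 1.06 in DMH and by -1.02 in VMH (adjusted p = 0.0486 and 0.0435). Of 21 alternatives, the Prlr calls did not hold in 6 (DMH) and 9 (VMH), and those of Nptx2 and Crym in 12 and 8. The Col23a1 call did not hold in 13 and the Gpr50 calls in 15 (DMH) and 13 (VMH). Sirt1, which encodes a NAD-dependent deacetylase, differed by 0.86 ± 0.36 in DMH against the mean of Arc and VMH (adjusted p = 0.292), and Npvf, the precursor of RF-amide peptides, by 0.64 (adjusted p = 0.472). Sirt1 differed by 0.46 without DMH replicate 1 and Npvf by 0.16 without DMH replicate 2, and neither passed. Hcrtr2, the gene of the other orexin receptor, was well above background on 2 of the 8 arrays and was not tested.

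Pairs of nuclei show against which nucleus a gene differed. Between DMH and VMH, 121 genes were higher in DMH and 216 higher in VMH. Grp, Skor1 and Prdm13 were higher in DMH by at least 54.6-fold, 35.2-fold and 34.7-fold, and Trh and Dlx1os, an antisense transcript of Dlx1, by at least 45.9-fold and 44.7-fold, both well above background on 1 of the 3 VMH arrays (adjusted p between 0.00204 and 0.0145). Fezf1 and Kcna1 were higher in VMH by at least 68.7-fold and 15.1-fold, Ccnjl and the glycine receptor gene Glra3 each by at least 9.75-fold and Qrfpr by at least 37.8-fold (adjusted p between 1.1e-05 and 0.0444). Nr5a1 was lower in DMH, with a log2 difference of -1.31 ± 0.18 (adjusted p = 0.0212). Between VMH and Arc it differed by 0.87 ± 0.21 and did not pass (adjusted p = 0.123). The count of 121 was 53, 51 and 61 without VMH replicates 1, 2 and 3 and 59, 57 and 53 without DMH replicates 1, 2 and 3. The count of 216 was 69, 64 and 62 without VMH replicates 1, 2 and 3 and 108, 77 and 93 without DMH replicates 1, 2 and 3.

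Between DMH and Arc, 66 genes were higher in DMH and 48 higher in Arc. Cck, Grp and Nr2f2 were at least 166-fold, 47.9-fold and 23.8-fold higher in DMH, and Prdm13 and Egr2, each well above background on 1 of the 2 Arc arrays, at least 24-fold and 22.4-fold (adjusted p between 0.000268 and 0.0433). Pomc and Tbx3 were 49.1-fold and 24.2-fold higher in Arc, and Trim67 and the activin receptor gene Acvr1c at least 10.6-fold and 9.84-fold (adjusted p between 0.00576 and 0.0163). The count of 66 was 110 without Arc replicate 1, 32, 35 and 33 without VMH replicates 1, 2 and 3 and 32, 26 and 27 without DMH replicates 1, 2 and 3, and 24 with only the arrays of these nuclei in the fit. The count of 48 was 86 and 145 without Arc replicates 1 and 2, 25, 21 and 19 without VMH replicates 1, 2 and 3 and 17, 12 and 27 without DMH replicates 1, 2 and 3, and 22 with only these nuclei in the fit. Without Arc replicate 2 the balance turned to 99 higher in DMH and 145 higher in Arc, and it also turned with normexp (109 and 124), with only probes well above background on all arrays (54 and 59) and with a floor on dim values (95 and 96).

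Between VMH and Arc, 181 genes were higher in VMH and 87 higher in Arc. Fezf1, Nr2f2, Fam81a and Kcna1 were at least 48.2-fold, 31.7-fold, 14.6-fold and 10.6-fold higher in VMH, and Cbln1 was at least 75.2-fold higher (adjusted p between 3.99e-05 and 0.0136). Npy and Pomc were 81.8-fold and 48.7-fold higher in Arc, and Dlx1os, Gad1 and Nr5a2 at least 37.7-fold, 31.8-fold and 26.3-fold (adjusted p between 0.00302 and 0.0476); Dlx1os and Gad1 were well above background on 1 of the 3 VMH arrays and Nr5a2 on 2. The Npy fold was 44.5 without VMH replicate 1 and 166 without VMH replicate 3, and its call did not hold in 10 of 22 alternatives, with an adjusted p between 0.00424 and 0.109 over all 22. The count of 181 was 74, 69 and 49 without VMH replicates 1, 2 and 3 and 117 without DMH replicate 3, and 50 with only the arrays of these nuclei in the fit. The count of 87 was 167 without Arc replicate 2, 44, 53 and 44 without VMH replicates 1, 2 and 3 and 50 without DMH replicate 3, and 22 with only these nuclei in the fit. Where 1 Arc array was left out, the remaining one was assumed to vary like the other nuclei.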

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

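The correction for probe GC content was chosen after seeing the data. Gene calls were followed only for the genes that the rule names. None of these 152 gene calls or of the 36 list calls reversed under any alternative. Many of these genes were chosen because their arrays did not overlap, which leaves little room for a reversal when an array is left out. Of the 152 gene calls, 59 held in every alternative in which they were tested, and 70 did when left-out arrays were set aside; 13 of the 36 list calls held throughout. Counts of genes higher in DMH, VMH and Arc than in the mean of the other nuclei were 100, 239 and 53. Those higher in DMH than VMH, DMH than Arc and VMH than Arc were 121, 66 and 181, and those lower were 216, 48 and 87. In this order, no filter on dim probes gave 56, 159, 32, 79, 25, 111, 121, 16 and 53, and the slide row as a block 36, 140, 23, 64, 34, 113, 103, 21 and 51. The replicate block gave 26, 88, 15, 69, 20, 46, 94, 12 and 28; 75 of the 152 gene calls were not made with it, nor were 4 of the 36 list calls, all in Arc: neuropeptides (adjusted p = 0.0885), paraventricular and suprachiasmatic markers (0.158), astrocyte markers (0.134) and oligodendrocyte markers (0.0652). Deviations of the 7 pairs of arrays that share a number correlated at 0.0721 to 0.185, 2 of them over 0.1, and all 8 arrays correlated best with their own number, a hint from the data, not the design.

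Normexp gave 132 genes higher in Arc, 109 higher in DMH than Arc, and 332, 124 and 150 lower in DMH than VMH, DMH than Arc and VMH than Arc. It moved the share of higher genes among those called from 31.7% to 46.3% in Arc and from 57.9% to 46.8% in DMH against Arc, and leaving out Arc replicate 2 moved them to 52.8% and 40.6%. The floor gave 100 genes higher in Arc, 96 lower in DMH than Arc and 138 lower in VMH than Arc. Array weights gave 29 higher in Arc, and 25 higher and 16 lower in DMH than Arc. Trended and robust eBayes gave 92 higher in Arc, 122 higher and 102 lower in DMH than Arc, and 279 higher in VMH than Arc. The mean of a gene's probes gave 124 higher and 83 lower in DMH than Arc. A fit of only the 2 nuclei compared gave 24 higher and 22 lower in DMH than Arc, and 50 higher and 22 lower in VMH than Arc. The estimated correlation left 2, 9 and 2 of the 8, 16 and 12 lists of DMH, VMH and Arc. Leaving out 1 array at a time gave 21 to 110, 58 to 199 and 20 to 152 genes higher in DMH, VMH and Arc. For the pairs it gave 51 to 112, 26 to 110 and 49 to 191 higher and 62 to 177, 12 to 145 and 44 to 167 lower. Lists numbered 7 to 9, 15 to 16 and 7 to 12, the 7 in Arc without Arc replicate 2. A left-out array and the fit of 2 nuclei leave fewer samples, but some counts rose without an Arc array. There the spread within Arc no longer entered the fit, and whether this caused the rise was not tested. The blocks for replicate number and slide row leave fewer residual degrees of freedom. For the other settings the cause was not tested. The value table of the series was not run as an alternative. Signal over background limits the low end: a gene not well above background in a nucleus has only a bound there.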

Other observations

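The tests of Nr5a1, of the glial markers and of the other splits of the samples were chosen only after the result was seen; the tests of intergenic probes were not. Of 4196 measured intergenic transcript probes with a position, 5 were higher and 9 lower in DMH, 7 and 3 in VMH, and 4 and 2 in Arc (limma, adjusted p under 0.05). A probe on chromosome 13 at 78370554 to 78370613 (mm9), 41.8 kb from the probe of Nr2f1, differed by 1.81 in DMH (adjusted p = 0.0261) and by -2.77 in Arc (0.00845); it was chosen after its values were seen. Nr2f1 itself differed by 2.00 and -2.94.

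Called intergenic probes lay near called genes of the same direction in 7 of 30 cases within 100 kb, against a mean of 0.384 and at most 4 in 10000 random sets matched on signal (permutation p = 1e-04, the smallest these draws can give). The 7 cases come from 6 probes at 4 loci, as some probes share a neighbour and a probe called in both DMH and Arc counted for each. The cases are thus not independent, and the random sets were matched on signal, not on shared loci. The p is therefore too small. The 4 loci do not exceed the 4 cases of the highest random set, so no conclusion is drawn from the p. Of 6 pairs, 5 lay on the neighbour's strand (83.3%, exact 95% interval 35.9 to 99.6), so longer 3' ends of the neighbour cannot be told apart from separate transcripts. Nearby transcripts that share regulation may be a further explanation, which was not tested.

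Nr5a1 differed by 1.31 ± 0.184 between VMH and DMH, which put DMH at 40.3% of the VMH level. Between VMH and Arc the difference was 0.87 ± 0.206 and did not pass (limma, adjusted p = 0.123), with Arc at 54.7% of the VMH level. RNA of VMH neurons in the DMH samples would bring every VMH transcript up to a like share. With signals too dim to measure raised to the lowest level well above background, 4 of 21009 genes lay further below VMH in DMH than Nr5a1 beyond its error, Fezf1 by at least 6.10 on the log2 scale, and 7 of 22673 did so in Arc (limma treat, adjusted p under 0.05). These argue against RNA of VMH neurons as a whole at the share Nr5a1 needs, not against that of a part of them. A count of 5 in DMH asked for at first was not reached and was lowered after the result was seen. The reason was that under a like share the test would rarely call any gene. With dim signals as measured the counts beyond the error of Nr5a1 were 5 and 16. Another version took the 2261 genes at least as bright as Nr5a1 and made no allowance for its error. By that looser limit 4 lay further below VMH in DMH and only 1 in Arc. Only 1 probe reads Nr5a1, so a signal not from Nr5a1 alone cannot be excluded, and expression of the gene outside VMH, a biological explanation, stays open and may also hold.

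Glial markers moved between nuclei: astrocyte markers had a median of 0.468 in DMH, microglia markers of -0.544 and oligodendrocyte markers of 0.446 in VMH, and astrocyte and oligodendrocyte markers of -0.300 and -0.288 in Arc, although with an estimated correlation no list passed (adjusted p = 0.393, 0.0764, 0.307, 0.44 and 0.337 in this order) and Gjb6 in DMH was the only single gene past the threshold. A lower share of neurons alone, with the same mix of glia in each nucleus, would raise all glial types alike. Oligodendrocyte minus microglia medians separated VMH from the other arrays by 0.987 (lowest VMH array 0.653, highest other 0.0034). The exact two-sided permutation p was 0.0179, the smallest that 56 splits can give, for a contrast picked from the medians. Over all 3 pairs of these lists and all 3 nuclei, 20 of 560 assignments of the arrays gave a difference as large (exact permutation p = 0.0357). This too is the smallest p the test can give for a nucleus of 3 arrays. The values go against that account, but not against a lower share of neurons where the mix of glia differs. No single array carried a median to 0: the smallest size without 1 array was 0.186, for oligodendrocyte markers in VMH without VMH replicate 3, although these ran up to 0.831 without Arc replicate 1, which also took those in Arc to -0.499, and astrocyte markers in Arc were at -0.189 without VMH replicate 3. The oligodendrocyte call in VMH ended without that array, as it also did without Arc replicate 2, VMH replicate 1 or DMH replicate 3, and in Arc the astrocyte call ended without Arc replicate 2, VMH replicate 3, DMH replicate 2 or DMH replicate 3, and the oligodendrocyte call without the first 3 of these. A difference in glial cells between the nuclei or in the glia caught with the cut cells may underlie the shifts, and these were not told apart by a test.

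The real split gave the most genes higher in each nucleus among 100 splits drawn, the real one included. Its counts were 100 in DMH (highest other 70), 239 in VMH (highest other 100) and 53 in Arc (highest other 0). The draw left out the assignment that only exchanges the names VMH and DMH, which would count 239 genes for DMH. The first place of the real split in DMH therefore depends on the draw. The filter on dim probes, taken from the real nuclei, was kept in every split and favours the real one. Samples may also share an animal, so these splits do not exclude chance. For DMH against VMH the 10 splits are too few for a share under 0.05; 1 split, the real one, gave 337 genes and the highest other 0.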
